A study of Mus musculus with 8 samples.

How the data were processed

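Polyadenylated RNA of TM3 cells was fragmented, and part of it was immunoprecipitated with an m6A antibody kit, per the labels' protocols. Both parts were sequenced on an Illumina instrument in paired-end mode. The labels name 8 libraries, 2 each of BPA RNA-seq, normal RNA-seq, BPA MeRIP and normal MeRIP. Groups and replicate numbers were taken from the sample titles.

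The count table was deposited as whole read counts per Ensembl mouse gene. Per the submitters' processing notes the tools were fastp 0.20.1, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.38.3, with GRCm39 and GRCh38 as builds and no role given for either. Whether the counting used strand or multi-mapping reads is not given in the sources used here. Gapdh, with many near-identical pseudogenes, had 104 and 26 reads in the normal libraries and 1 and 0 in the BPA libraries, so counts of genes with close copies are uncertain. The 4 count columns carry a condition and a number but no assay. They were taken as the RNA-seq libraries because the notes list featureCounts and DESeq2 and the design text names RNA-seq as input. As a check, their gene levels were ranked against the summed RPM of the peaks over 2166 genes. The Spearman correlation was 0.413 with the input and 0.328 with the IP in normal cells, and 0.324 and 0.288 in BPA cells. The change between conditions had a correlation of 0.253 with the change in input and -0.0335 with the change in IP. Of the 12404 gene IDs, 12271 (98.9%) had a symbol in the gene name table used.

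The RPM values of the peaks were deposited by the authors as 1 pooled value per condition for the IP and for the input. The peak caller and the total behind the RPM scale are not given in the sources used here. The RPM values were whole multiples of a fixed step in 100% of the peaks in each column, within 0.1 read, so the reads could be recovered. The recovered totals behind the RPM scale were 5402180 and 1703690 reads for the normal IP and input and 3908370 and 818212 for the BPA IP and input. These are not sequencing depths, since the RPM of the peaks alone sums to between 826089 and 894159 per column. The log2 fold change of each peak was deposited by the authors, as the change of IP over input in BPA against normal. In the 1016 peaks with at least 100 reads in all 4 columns it exceeded the log2 ratio of ratios of the RPM columns by a constant of 0.78. Where a column holds 0 that ratio is undefined, so the constant was not checked there. The p-value and false discovery rate of each peak were deposited by the authors, and their test is not given in the sources used here. Peak starts were shifted from the 0-based file to 1-based coordinates. The build was read as GRCm39, since 11.3% of 3176 peaks lay inside the span of their gene in the reference table of GRCm38. No GRCm39 annotation was used here, so exons, introns and UTRs of peaks are not analysed here. No per-sample column of these tables was left unused.

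Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total 15), robust dispersion estimates, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05 over 8645 genes. Standard errors of log2 fold changes were derived from the F statistic. CPM used TMM-scaled library sizes. DESeq2 1.42.0 was run as an alternative. Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, and with an estimated correlation) and with fry, for lists with at least 5 tested members. The 27 lists covered steroidogenesis, lipid metabolism, autophagy and lysosome, the m6A machinery, stress responses, cell death, proliferation, hormone receptors, energy metabolism, inflammation, immediate early genes, extracellular matrix, other testis cell types, mitochondrially encoded mRNAs and noncoding RNAs. Genes of a group at 0 reads are given as a bound against a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

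The authors' peaks were counted by direction with an exact binomial test. RNA changes of genes with higher and with lower peaks were compared by a two-sided permutation test of the difference of medians with 100000 resamples, with scipy and numpy. For the IP and input changes of peaks, 1 RPM was added before taking log2. A gene-level test of m6A enrichment had been planned for per-library MeRIP counts and was not run, since the count table used here holds the RNA-seq libraries alone.

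The groups, the tests, the gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. The rule named Map1lc3b, Mettl3, Mettl14, Wtap, Fto, Alkbh5, Star, Cyp11a1, Cyp17a1, Hsd3b1, Sqstm1 and Becn1 in any case. It also named the 12 genes with the largest rise and fall past the threshold with an average log2 CPM of at least 3, of which there were 0, and the 3 members with the smallest p of lists that passed. For peaks it named the 6 higher and 6 lower with the smallest adjusted p of the authors, with ties ordered by larger absolute fold. It also named all peaks in the lists autophagy core, steroidogenesis and m6A machinery. Because it named 0 genes past the threshold, a further rule was set after the data were seen. It took up to 12 genes per direction with an unadjusted p under 0.05, an average log2 CPM of at least 7 and groups that do not overlap, by smallest p, and 104 higher and 5 lower genes met it. That rule was revised once after its output was seen, when a mean level replaced a minimum in every library. List members outside the rule were also chosen after their values were seen.

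Alternatives fixed at that time were DESeq2's size factors in edgeR, the legacy quasi-likelihood method, no filter, a filter of 1 CPM in 2 libraries, a replicate block, leaving out each library, DESeq2, a fold threshold, an adjusted p of 0.01 for peaks and 1 peak per gene. Alternatives chosen after the data were seen were DESeq2 on all genes, a mean of at least 1000 reads, removal of the constant from the peak fold change, a minimum of more than 10 reads per peak column, an exact noncentral hypergeometric test of the recovered reads, a test with the input reads scaled by the spread between replicates, and peak direction from the IP alone.

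The edgeR and DESeq2 steps were tested on simulated data with 200 genes changed 4-, 16- or 64-fold between 2 BPA and 2 normal RNA-seq libraries. With a biological coefficient of variation of 0.2, edgeR recovered 100% of the changed genes of each fold over 8632 genes. A further simulation took the spread of the real libraries, with 1 value per gene for both groups. There edgeR recovered 3.13% of the 4-fold, 28.6% of the 16-fold and 49.1% of the 64-fold changes over 8030 genes. DESeq2 recovered 6.25%, 32.1% and 70.2% of them, and also called 181 of 7853 unchanged genes, where edgeR called 2. At that spread a list of 23 genes lowered 4-fold had a camera p of 0.0941 and an unchanged list of 22 genes had 0.0880, so camera did not separate them. In a simulation with the same spread and no other changed gene, a lowered list of 22 genes had a camera p of 3.10e-06 and an unchanged list of 23 genes had 0.278. At the lower spread the lowered list of 25 genes had a camera p of 1.49e-42 and the unchanged list 0.707. The recovery of reads from RPM returned the simulated depths for 100% of 3331 peaks. The permutation test gave p = 0.453 for 1700 simulated genes with no difference and p = 0.000200 for a difference of 0.4.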

Results

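TM3 is an established line of mouse Leydig cells, the testosterone-producing cells of the testis. Bisphenol A (BPA) is a building block of plastics and has estrogen-like activity. Cells exposed to BPA were compared with normal cells by RNA-seq and by MeRIP-seq, in which an antibody pulls down RNA fragments that carry N6-methyladenosine (m6A). The design text states that the RNA-seq libraries also served as the input of the MeRIP-seq. Each of the 4 groups had 2 libraries, and the labels used here give no dose and no exposure time. The gene count table covered 12404 genes in the 4 RNA-seq libraries, with 10455643 and 7517482 reads in the normal libraries and 8813870 and 6305121 reads in the BPA libraries. The m6A data were a table of 3331 differential peaks in which the authors had pooled the replicates. Whether the replicates came from separate cultures is not stated in the labels, so the p-values measure the spread between these libraries, which may be technical.

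The first comparison asked which RNAs differed between BPA-exposed and normal cells. Among abundant genes the smallest p-values belonged to genes with more reads in BPA. Efna5, which encodes a membrane-bound ligand of Eph receptors, had 509 ± 206 counts-per-million (CPM) in BPA and 80.7 ± 28.5 in normal cells (SD, n = 2 each). Anp32b, a histone chaperone gene, had 3690 ± 81.5 against 1631 ± 251 CPM, and Hsp90aa1, the inducible cytosolic HSP90, had 4945 ± 631 against 2537 ± 198 CPM. Nras, a small GTPase gene, had 30.8 ± 42.4 CPM in BPA and 225 ± 9.47 in normal cells, and Ndrg1, a hypoxia-inducible gene, had 45.3 ± 7.04 against 226 ± 147 CPM. None of these differences passed the test over all genes. In a fit of the 1756 genes with a mean of at least 1000 reads alone, log2 fold changes lay lower by a median of 0.27. There Anp32b had 0.89 in place of 1.18, Hsp90aa1 0.68 in place of 0.96 and Ndrg1 -2.61 in place of -2.33. The size of these differences thus depends on the genes used for scaling.

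edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 8645 tested genes at an adjusted p of 0.05, and the smallest adjusted p was 0.372. At an unadjusted p under 0.05 there were 833 genes, 208 with higher and 625 with lower counts in BPA, where the nominal rate of 5% gives 432. On simulated counts with the spread of these libraries and no changed gene, 6.84% of 8059 genes had an unadjusted p under 0.05 in edgeR, above that rate. DESeq2 on the same genes called 264, of which 45 were higher and 219 lower. Of those 264, 234 had 10 or fewer reads in both libraries of the lower group. On the same simulated counts DESeq2 called 200 of 8059 genes and edgeR called 0. The simulation gave both groups the same spread per gene, whereas the real BPA pair varied more than the normal pair. It therefore does not give the share of false calls among the 264. The groups did not overlap in 40.0% of the tested genes, and chance gives 33.3%. With the size factors of DESeq2 in place of TMM the median log2 fold change of all tested genes moved by 0.14, and the unadjusted split became 328 higher and 429 lower, still with 0 calls. The split turned to 397 higher and 193 lower with no filter on low counts and to 164 and 52 with replicate number as a block, so it has no settled direction.

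Replicate libraries differed widely. The Spearman correlation across the tested genes, which are not independent replicates, was 0.549 between the BPA libraries and 0.741 between the normal libraries, and it lay between 0.572 and 0.638 for pairs across the conditions. Over all 12404 genes of the count table, tested or not, the median gene had 15 and 2 reads in the BPA libraries and 233 and 150 reads in the normal libraries. Wtap, which encodes a subunit of the m6A writer complex, had 3632 reads in BPA replicate 1 and 3 reads in BPA replicate 2. Fto, an m6A demethylase gene, had 645 and 10 reads in the BPA libraries and 918 and 2 in the normal libraries. Abundant genes varied less, as for Hsp90ab1 with 61555 and 43476 reads in BPA and 70554 and 34469 in normal cells. The median biological coefficient of variation was 1.46 over the tested genes and 0.573 over the 1756 genes with a mean of at least 1000 reads.

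**Figure D1:**
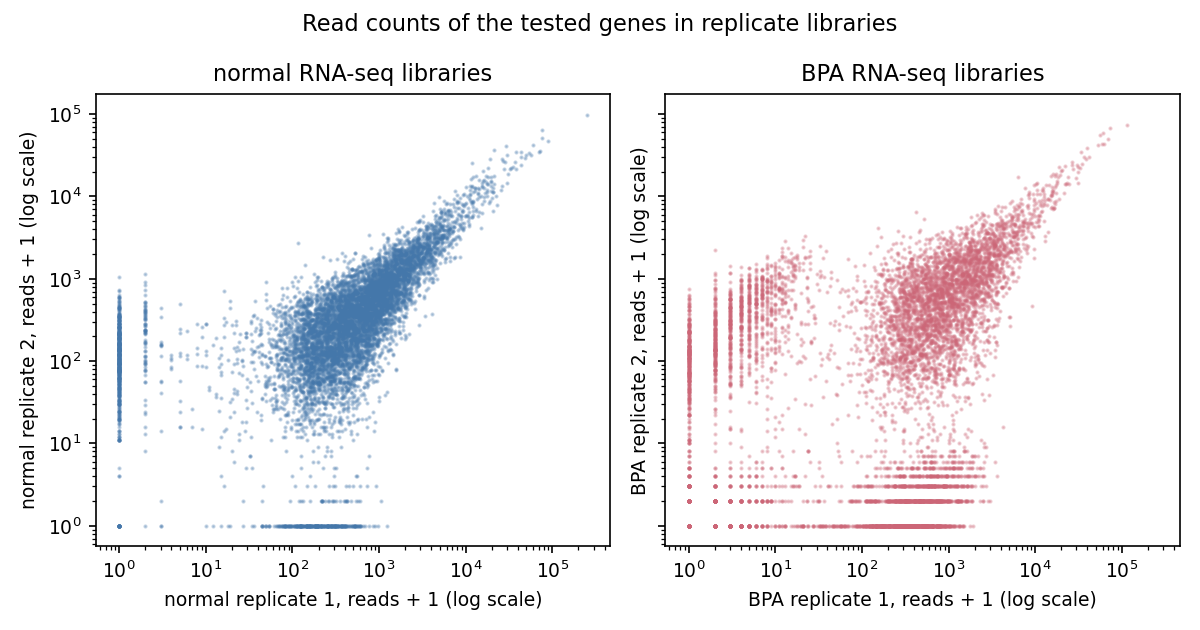
Reads per tested gene in replicate 1 (x axis) and replicate 2 (y axis) of the normal libraries (left) and the BPA libraries (right), both as reads + 1 on log scales, 1 point per gene. Among genes with a mean of at least 100 reads those with 10 or fewer reads in 1 of the libraries make up 37.1% in the BPA pair and 9.75% in the normal pair.

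Genes with more reads in BPA at an unadjusted p under 0.05 also included Mia2, which acts in the export of large cargo from the endoplasmic reticulum, with a log2 fold change of 2.73 ± 0.74 (SE). Ifrd1, a transcriptional co-regulator gene, had 1.68 ± 0.46, the zinc finger gene Zbtb14 3.54 ± 1.00, and the small GTPase gene Arf6 3.90 ± 1.11 on the same scale. Eif4a2, a translation initiation helicase gene, had 1.46 ± 0.44. S100pbp had 552 ± 277 CPM in BPA and 120 ± 40.7 in normal cells, and Tmem168 696 ± 569 against 126 ± 98.9 (SD, n = 2 each). Rnf219 had a log2 fold change of 3.64 ± 1.12 (SE). Single libraries moved some of these log2 values: without BPA replicate 1 Rnf219 had 1.49, without BPA replicate 2 Zbtb14 had 2.18, Tmem168 1.22, S100pbp 1.57 and Arf6 2.95, and without normal replicate 2 Arf6 had 5.76 and Tmem168 3.65. With Efna5, Anp32b, Hsp90aa1 and mt-Nd2 these were 12 genes, chosen so that both BPA libraries lay above both normal libraries. DESeq2 called all 12, with adjusted p from 0.00202 for Anp32b to 0.0337 for Rnf219. They were chosen by smallest edgeR p from the same counts, so this is no independent support. Over all tested genes DESeq2 called 45 higher and 219 lower, a balance that the genes named here do not reflect. Of genes with fewer reads in BPA, Cltb, a clathrin light chain gene, had a log2 fold change of -1.79 ± 0.76, Lrrc59 -1.47 ± 0.65 and Snrnp70, of the U1 spliceosomal particle, -1.77 ± 0.80. DESeq2 called none of Nras, Ndrg1, Cltb, Lrrc59 and Snrnp70, with adjusted p from 0.272 to 0.414. Nras had a log2 fold change of -2.63, which was -8.21 without BPA replicate 1, and Ndrg1 had -2.33, which was -1.36 without normal replicate 1. Cltb had -1.23 without BPA replicate 1 and -2.45 without BPA replicate 2. In the fit of genes with a mean of at least 1000 reads alone, Mia2 had 2.44, Ifrd1 1.41 and Eif4a2 1.19. Cltb had -2.04 and Lrrc59 -1.74 in that fit. These 17 genes were chosen after their values were seen.

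The series title names Map1lc3b, which encodes the autophagosome protein LC3B, as an m6A target. Map1lc3b had 416 and 350 reads in the normal libraries and 2 reads in each BPA library, or 40.5 ± 6.25 against 0.303 ± 0.09996 CPM (SD, n = 2 each). The pooled ratio of BPA to normal was 0.00724, with an exact 95% interval for counting error of 0.00197 to 0.0186. edgeR gave a log2 fold change of -7.05 ± 3.28 (SE), p = 0.0514 and an adjusted p of 0.372, so the difference did not pass the test against the spread between libraries. DESeq2 gave an adjusted p of 0.0846 on the tested genes and 0.0286 on all genes of the table. Over the other settings the adjusted p ranged from 0.0968 to 1.00. Of 1167 genes with 32.4 to 50.6 CPM and at least 100 reads in both libraries in normal cells, 199 (17.1%) also had 10 or fewer reads in both BPA libraries.

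The core autophagy genes were mostly lower in the BPA libraries. Of 29 tested members, 23 had negative and 6 positive log2 fold changes, with a median of -0.76, also with the 3 members at 0 reads in BPA set to their bound. Rb1cc1, which encodes the ULK complex scaffold FIP200, had 825 and 508 reads in normal cells and 9 and 3 in BPA. Atg13, of the same complex, had 892 and 56 reads in normal cells and 0 in both BPA libraries. That was at least 228-fold lower by counting error alone, against a floor of 3 counts over the group, a bound carried mostly by normal replicate 1. Such bounds leave out the spread between libraries, in which replicates of 1 group could differ as widely (Wtap 3632 and 3 reads in BPA). Ulk2, an autophagy kinase gene, had 355 and 317 reads against 0 and 0, at least 162-fold lower by counting error alone. Atg12, of the LC3 conjugation machinery, had 849 and 868 against 122 and 1 reads, while the cargo receptor gene Sqstm1 had 1423 and 641 against 1002 and 142, and Becn1, of the class III PI3-kinase complex, had 1219 and 287 against 683 and 77. Gabarap, an LC3 homologue, had 2316 and 545 reads in normal cells and 1998 and 1793 in BPA.

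edgeR called 0 of these 29 genes over all genes and 0 adjusted over the list alone, where the smallest adjusted p was 0.187. At an unadjusted p under 0.05 there were 3, Rb1cc1, Atg13 and Atg12, all lower, and DESeq2 called 3, Rb1cc1, Atg13 and Ulk2. limma's camera placed the list lower with p = 0.0259 and an adjusted p of 0.260 over 22 lists, and the adjusted p = 0.863 with an estimated correlation. The camera p was 0.0434 and 0.1995 without BPA replicate 1 and 2, and 0.235 and 0.00400 without normal replicate 1 and 2. fry's test of change in either direction gave an adjusted p of 0.0374, and its test of movement one way gave 0.239. The mitosis list, with 11 positive and 11 negative members, also passed the test of change in either direction, with an adjusted p of 0.0469.

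**Figure D2:**
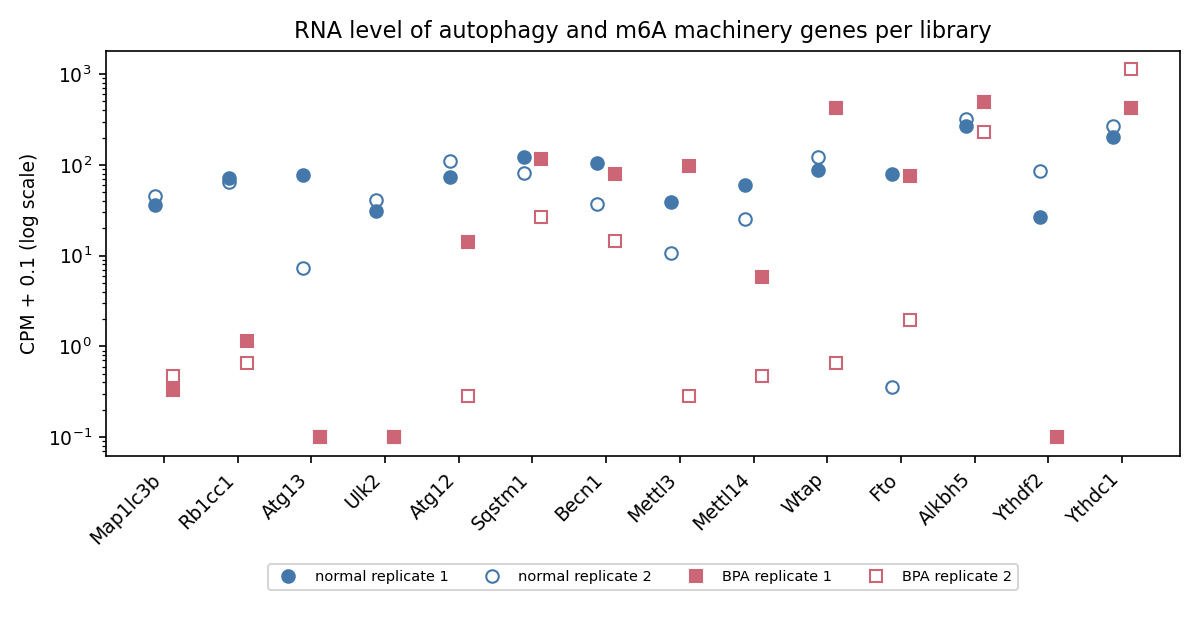
CPM + 0.1 on a log scale for 14 autophagy and m6A machinery genes in each of the 4 RNA-seq libraries; filled and open symbols are replicates 1 and 2. Map1lc3b, Rb1cc1, Atg13, Ulk2 and Ythdf2 lie low in both BPA libraries (symbols of libraries at 0 reads coincide at 0.1), while Mettl3, Wtap and Fto differ between replicates of a group.

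The genes of the m6A machinery showed no common direction, with 12 positive and 9 negative log2 fold changes among 21 tested. Mettl3, the catalytic subunit of the writer complex, had 452 and 82 reads in normal cells and 830 and 1 in BPA. Its partner Mettl14 had 691 and 195 against 49 and 2, with a log2 fold change of -3.61 ± 1.91 (SE) in edgeR, which was -6.77 without BPA replicate 1 and -2.90 without BPA replicate 2. Wtap had 105 ± 23.0 CPM in normal cells and 211 ± 298 in BPA, and the demethylase gene Alkbh5 had 296 ± 37.2 against 364 ± 188 (SD, n = 2 each). The nuclear reader gene Ythdc1 had 2334 and 2091 reads in normal cells and 3612 and 6074 in BPA, at an unadjusted p of 0.0108. The reader gene Ythdf2 had 306 and 671 against 0 and 0 reads, at least 235-fold lower by counting error alone, a bound carried mostly by normal replicate 2. The writer subunit gene Rbm15b had 693 and 133 against 0 and 0, at least 199-fold lower by counting error alone, carried mostly by normal replicate 1. edgeR called 0 of these genes, also adjusted over the list alone, 3 passed an unadjusted p of 0.05, and DESeq2 called Ythdf2 and Rbm15b. The list had a camera adjusted p of 0.923.

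Steroidogenic genes were sparse in this table. Of the 19 listed, 5 were in the table and 4 were tested, and Star, Cyp11a1, Cyp17a1 and Hsd3b1 were not among its rows and are not analysed here. Scarb1, a cholesterol uptake receptor gene, had 458 and 150 reads in normal cells and 1677 and 331 in BPA, and Tspo, of the outer mitochondrial membrane, had 12 and 36 against 320 and 61. Por had 554 and 327 against 827 and 350, and Fdxr 1247 and 549 against 553 and 375. edgeR called 0 of the 4, 0 had an unadjusted p under 0.05, DESeq2 called 0, and the smallest adjusted p over the list alone was 0.174. With 4 tested members the list was below the minimum of 5 for camera.

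Of the stress and growth lists, the heat shock proteins had 7 of 11 tested members with positive log2 fold changes, a camera p of 0.0354 and an adjusted p of 0.260. The mitochondrially encoded mRNAs had 8 of 12 positive, with mt-Nd2 at 0.97, mt-Nd6 at 1.06 and mt-Nd5 at 0.77 on the log2 scale, all with unadjusted p under 0.05. Adjusted over the list alone, mt-Nd2 reached 0.0502, and camera gave the list an adjusted p of 0.310. In an edgeR fit of genes with a mean of at least 1000 reads alone, mt-Nd2 had 0.67. There the smallest adjusted p over the 7 abundant list members was 0.138. Among all 12 tested members the median of 0.31 and mean of -0.27 differed in sign. The structural and nuclear noncoding RNAs had 6 of 7 positive, a camera p of 0.0287 and an adjusted p of 0.260. Glycolysis and hypoxia genes had 18 of 23 negative, with a camera p of 0.0594 and an adjusted p of 0.310. Immediate early genes had 8 of 14 negative and a camera adjusted p of 0.923, with Dusp6, a phosphatase that acts on ERK, at 1553 and 592 reads in normal cells against 23 and 7 in BPA. For the 3 lists with a camera p under 0.05, which are autophagy core, heat shock proteins and structural and nuclear noncoding RNAs, the adjusted p = 0.863 with an estimated correlation in each.

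In the other lists the numbers of positive and negative log2 fold changes were 12 and 7 for cholesterol synthesis, 10 and 6 for fatty acid and lipid droplet genes, 11 and 16 for the lysosome, and 9 and 15 for the amino acid and integrated stress response. They were 10 and 9 for ER chaperones and the unfolded protein response, 14 and 8 for NRF2 and metal response genes, 9 and 10 for p53 targets and 4 and 12 for apoptosis regulators. DNA replication had 14 and 10, mitosis 11 and 11, hormone and xenobiotic receptors and their targets 4 and 6, and nuclear-encoded oxidative phosphorylation 11 and 13. NF-kB and inflammatory genes had 5 and 7, interferon-stimulated genes 4 and 2, and extracellular matrix and stromal genes 9 and 13. Their camera adjusted p lay between 0.452 and 0.923. edgeR called 0 of the 407 listed genes tested, adjusted over all genes or over the list alone, 8 were higher and 18 lower at an unadjusted p under 0.05, and DESeq2 called 4 higher and 9 lower. Markers of other testis cells were few: Clu and Wt1 of the Sertoli cell list, Cd68 of the macrophage list and Acta2 of the smooth muscle and endothelial list were tested, and no germ cell marker was. Acta2 had 80 and 352 reads in normal cells and 498 and 1270 in BPA, and Cd68 had 0 and 59 against 174 and 436.

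Among the 1756 genes with a mean of at least 1000 reads, a set chosen after the data were seen, glycolytic and hypoxia-inducible genes mostly had lower counts in BPA. All 10 abundant members of that list had negative log2 fold changes, with a median of -0.77, and camera gave the list an adjusted p of 0.000448 over 13 lists, which was lost with an estimated correlation (0.775) and with fry (0.417). The enzyme genes Ldha (-1.06 ± 0.63, SE), Aldoa (-1.14 ± 0.72), Pgk1 (-0.79 ± 0.51), Eno1 (-0.76 ± 0.52) and Tpi1 (-0.71 ± 0.45) and the hypoxia-inducible Ndrg1 (-2.61 ± 0.93) were among them. With DESeq2's size factors the median was -0.76. Without BPA replicate 1, BPA replicate 2, normal replicate 1 or normal replicate 2 the camera adjusted p was 0.0882, 0.190, 0.0652 and 0.000709. edgeR called 0 of the 1756 genes, with 52 higher and 25 lower at an unadjusted p under 0.05. For these genes the log2 fold changes lay lower by a median of 0.27 than in the fit of all 8645 genes.

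Extracellular matrix genes mostly had lower counts in the same set. Among all tested genes 13 of the 22 tested members were also negative, with a median of -0.21. There camera, which compares a list with the other genes, placed it higher (adjusted p 0.923). It did so under every other camera setting outside the abundant set. In the abundant set 13 of 18 were negative, with a median of -0.55 (-0.53 with DESeq2's size factors) and a camera adjusted p of 0.00372, which was lost with an estimated correlation (0.775) and with fry (0.274). Col6a1 (-1.49 ± 0.69, SE), Col5a1 (-1.28 ± 0.76), Col3a1 (-0.76 ± 0.34) and Fn1 (-0.59 ± 0.32) were lower, while Thbs1 (0.50 ± 0.46) was higher. Without each library in the same order the camera adjusted p was 0.385, 0.427, 0.0163 and 0.05001. Adjusted over the list alone, edgeR called 0 members of either list, with smallest adjusted p of 0.105 and 0.296. The other 11 lists had camera adjusted p between 0.224 and 0.994 in this set.

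**Figure D3:**
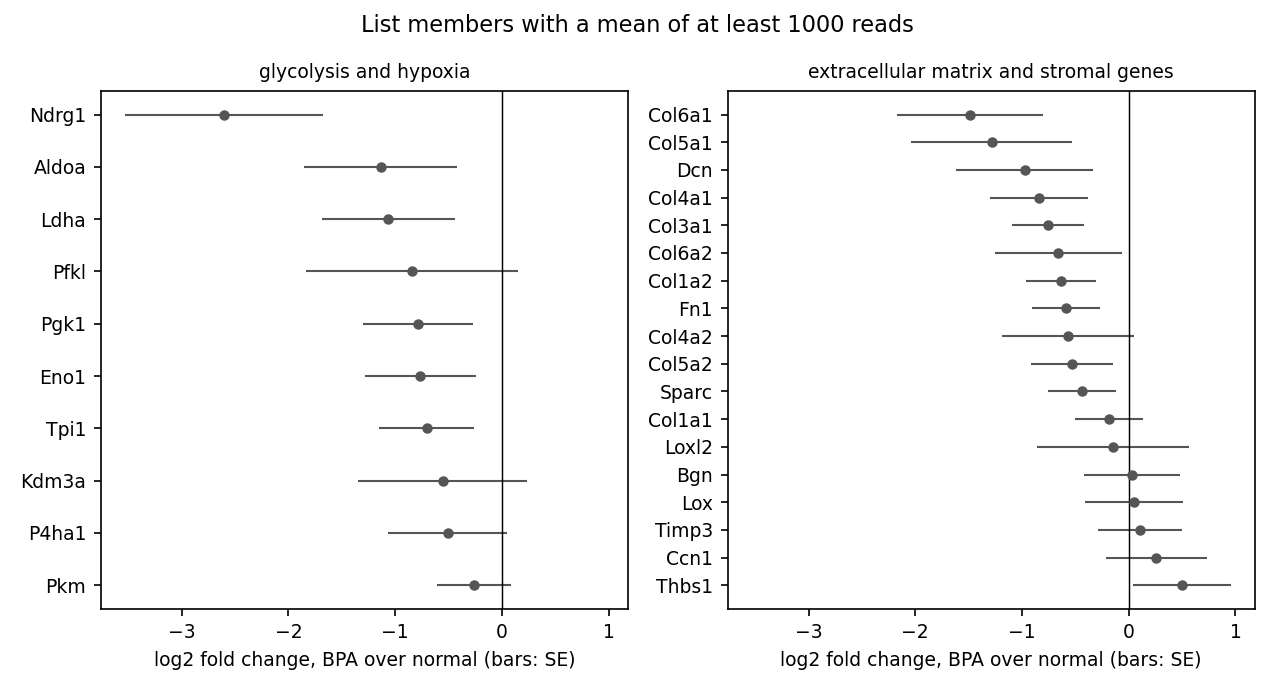
Log2 fold change of BPA over normal (x axis) with its SE for members with a mean of at least 1000 reads of the glycolysis and hypoxia list (left) and the extracellular matrix list (right), 1 point per gene. All 10 members on the left and 13 of 18 on the right lie below 0.

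The m6A comparison asked which RNA regions differed in methylation. In the table deposited by the authors, 2291 peaks were higher and 1040 lower in BPA, in 2295 genes. Higher peaks alone occurred in 1403 genes, lower peaks alone in 584 and both in 308. The 68.8% share of higher peaks had an exact two-sided binomial p of 1.48e-106, which describes peaks and not replicates. The share was 58.7% of 1362 peaks with more than 10 reads in all 4 columns. It was 52.4% of 1016 peaks with at least 100 reads in all 4 columns, and 40.8% of these without the constant in the authors' fold change. In the authors' deposited table every peak had an adjusted p of 0.0147 or less. Map1lc3b had a peak on chromosome 8 from 122323383 to 122323482 (GRCm39, forward strand), with 246 reads-per-million units (RPM) in the normal immunoprecipitate (IP) and 200.6 in the BPA IP, and 197 RPM in the normal input against 4.89 in the BPA input. The authors' deposited table gives it a log2 fold change of 5.81 with an adjusted p of 4.48e-15, and the BPA input value came from 4 reads. All RPM values of peaks are the pooled values of the authors' deposited table, with no replicate error. The median peak had 13.4 RPM in the BPA input and 167 in the normal input, though the sums over peaks were 894159 and 884773. The BPA input was thus concentrated in fewer peaks. The excess of higher peaks cannot be told apart from an effect of this scaling. The IP exceeded the input in 47.7% of the peaks in normal cells and in 62.5% in BPA.

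The other autophagy peaks were in Nbr1, Rb1cc1 and Uvrag. Rb1cc1 had a peak on chromosome 1 from 6310415 to 6310489, with 59.98 RPM in the normal IP and 167 in the BPA IP, and 157 RPM in the normal input against 3.67 in the BPA input. The autophagy receptor gene Nbr1 had a pair of peaks on chromosome 11, from 101471857 to 101471906 and from 101471932 to 101471956, whose log2 fold changes were 7.22 and 4.87 in the authors' deposited table. Uvrag had a spliced peak on chromosome 7 between 98653797 and 98665783, with 200.7 RPM in the normal IP, 0 in the BPA IP, 0 in the normal input and 2.44 in the BPA input. Of the steroidogenesis list, Por had a peak on chromosome 5 from 135764010 to 135764159 with 117 input reads in normal cells and 0 in BPA, and a log2 fold change of 8.42 in the authors' deposited table.

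Peaks in genes of the m6A machinery were more often lower, 6 of 10, and Fisher's exact test of genes with peaks in 1 direction gave p = 0.0530 and an adjusted p of 0.583 over 11 lists. The Mettl3 peak on chromosome 14 between 52534215 and 52534410 had 306 RPM in the normal IP and 0.26 in the BPA IP, with 227 and 403 RPM in the inputs. The Wtap peak on chromosome 17 from 13193411 to 13193435 had 433 RPM in the normal IP and 0.26 in the BPA IP. The Ythdc1 peak on chromosome 5 from 86983951 to 86983975 had 419 and 0.51 RPM in the same libraries. Their log2 fold changes in the authors' deposited table were -10.28, -10.70 and -10.54, and their BPA IP values came from 1, 1 and 2 reads. Hnrnpc on chromosome 14 (52311909 to 52311958) had -7.04, with 1 read in the BPA IP, and Hnrnpa2b1 on chromosome 6 (51443984 to 51444165) had -1.47 in the authors' deposited table. Higher values in the authors' deposited table were 12.15 for Igf2bp2 on chromosome 16 (21880614 to 21880638), 9.71 for Ythdf1 on chromosome 2 (180552963 to 180553012) and 5.004 for Zc3h13 on chromosome 14 (75560685 to 75560734). These 3 folds rest on counts at or near 0, with 0 reads in the normal IP for Igf2bp2, 0 in the BPA input for Ythdf1, and 0 in the normal IP and 2 in the normal input for Zc3h13. Fmr1 had a peak of each direction on chromosome X, -12.62 at 67759498 to 67759572 and 3.83 at 67760373 to 67760522 in the authors' deposited table, and the former rests on 0 reads in the normal input and 2 reads each in the BPA IP and input.

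Among the peaks with the smallest adjusted p in the authors' deposited table, those higher in BPA lay in Gm4739, Pdzd8, Timp3, Hmgn2, Srsf3 and Uso1, with log2 fold changes from 5.51 to 6.13. The Timp3 peak, in a gene for an inhibitor of matrix proteases, was on chromosome 10 from 86183027 to 86183051, with 37.0 RPM in the normal IP, 668 in the BPA IP, 541 in the normal input and 350 in the BPA input. Those lower in BPA lay in F11r, Gm10243 and the Rpl35a pseudogenes Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4 and Rpl35a-ps6, with log2 fold changes from -5.39 to -3.63 in the authors' deposited table. That table gives the adjusted p of all these higher and lower peaks as 0. Ties were ordered by larger absolute fold, so both fold ranges may follow from the choice. The Rpl35a pseudogene peaks had 945 to 1159 RPM in the normal IP and 196 to 197 in the BPA IP. Such near-identical copies can share reads, so these 4 peaks may count the same fragments and are uncertain. The F11r peak, in a tight junction protein gene, was on chromosome 1 from 171289392 to 171289466, with 702 and 48.1 RPM in the normal and BPA IP.

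Both the IP and the input differed between conditions in higher and in lower peaks, in different proportions. Peaks higher in BPA had a median of 126 RPM in the normal IP and 236 in the BPA IP, but 184 RPM in the normal input and 7.33 in the BPA input. Peaks lower in BPA had medians of 305 and 119 RPM in the IP and 126 and 394 in the input. In 1423 higher peaks (62.1%) and 235 lower peaks (22.6%) the BPA input held 10 or fewer reads. The BPA IP held 10 or fewer reads in 372 lower peaks (35.8%) and in 0 higher ones, the normal input in 268 lower peaks (25.8%) and 81 higher ones (3.54%), and the normal IP in 255 higher peaks (11.1%) and 0 lower ones. Of the higher peaks, 647 (28.2%) had no higher IP value in BPA than in normal cells. Across peaks, which are not replicates, the log2 fold change in the authors' deposited table had a Spearman correlation of 0.691 with the change in IP and -0.754 with the change in input.

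**Figure D4:**
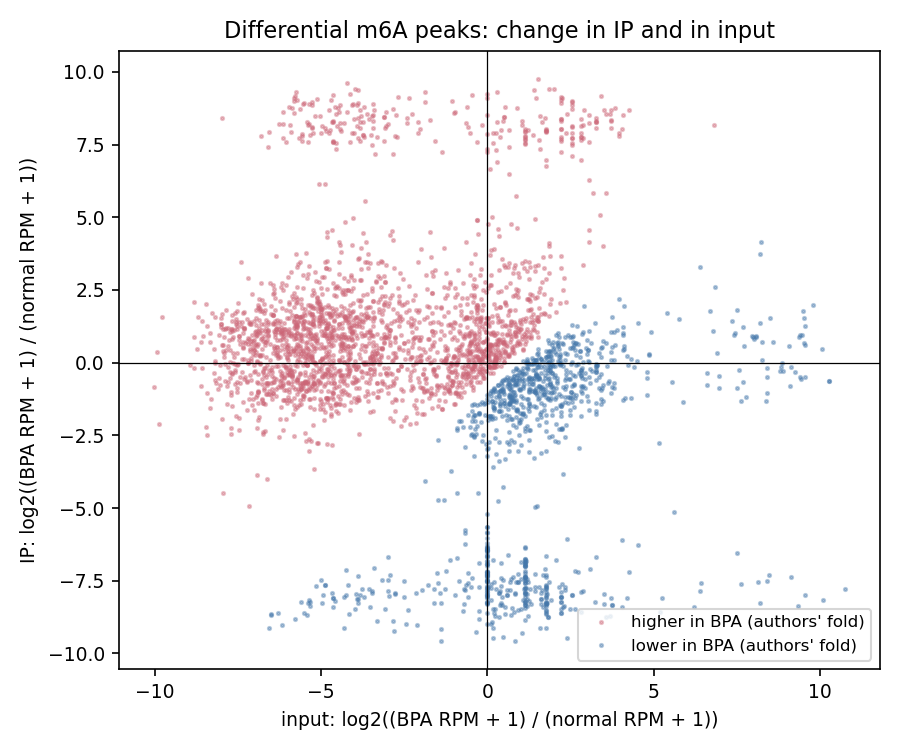
Change of each of the 3331 peaks in the input (x axis) and in the IP (y axis), both as log2 of BPA over normal RPM with 1 RPM added. Peaks higher in BPA by the authors' fold (red) extend to the left, with a median input change of -3.88, and peaks lower in BPA (blue) have a median IP change of -1.48.

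Genes with higher m6A peaks tended to have less RNA in BPA than genes with lower peaks. The median RNA log2 fold change was -0.07 over 1232 genes with higher peaks alone and 0.34 over 511 genes with lower peaks alone. The difference of -0.41 had a permutation p of 1e-05 (two-sided, 100000 resamples of genes), the smallest these resamples can give. Genes are not independent replicates, and the RNA-seq libraries are also the input of the m6A ratio, so the same reads enter both sides. When the direction of a peak was taken from the IP alone, the difference was -0.03 with a permutation p of 0.611. Across 2041 genes the RNA log2 fold change had a Spearman correlation of 0.238 with the change in peak input and -0.0427 with the change in IP.

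No gene passed edgeR's test, so the planned exact test of peak direction against RNA direction had 0 genes. At an unadjusted p under 0.05, 26 genes with higher peaks had more RNA and 43 less, while 21 genes with lower peaks had more RNA and 1 less, with a Fisher's exact p of 9.44e-07. Among the DESeq2 calls the numbers were 3, 30, 4 and 0, with a Fisher's exact p of 0.000530. Rb1cc1 was among the genes with a higher peak and a DESeq2 call of lower RNA, with 3 BPA input reads in its peak. The RNA-seq reads are also the input of the peak ratio, so few BPA reads give both a higher peak and lower RNA, and these p-values do not test a link between m6A and RNA level.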

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

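DESeq2 on all genes, the mean of at least 1000 reads and the further settings for peaks (removal of the constant, the minimum of more than 10 reads, the exact test of reads, the scaled input reads and the IP alone) were chosen after the data were seen. With edgeR the count of 0 genes held under DESeq2's size factors, the legacy method, both other filters and the mean of at least 1000 reads. The fold threshold was applied to the 0 calls of the main fit and could only give 0. At an unadjusted p under 0.05 the higher and lower genes were 328 and 429 with those size factors, 117 and 1095 with the legacy method, 397 and 193 with no filter and 209 and 429 with 1 CPM. DESeq2 called 45 higher and 219 lower genes, and 203 and 436 on all genes; of the former 264, 234 had 10 or fewer reads in both libraries of the lower group. Leaving out each library in turn gave 0 to 4 higher genes (2 without normal replicate 1 and 4 without normal replicate 2) and 0 to 0 lower ones; the lone library was then assumed to vary like the other group. The labels give the groups the same replicate numbers, and the differences between replicates had a correlation of -0.000963 across genes. That gives no sign of pairing, but the wide spread between libraries could hide a shared batch, so pairing is not excluded. With the replicate block edgeR called 0 genes higher and 0 lower (164 and 52 at an unadjusted p under 0.05), and camera called 0 lists. The replicate block gave Map1lc3b a log2 fold change of -7.03 and moved the RNA difference of genes with higher and lower peaks to -0.44.

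Map1lc3b was lower under every setting that tested it (the mean of at least 1000 reads leaves it out), with log2 fold changes from -7.36 to -6.70 without each library, and passed the threshold only with DESeq2 on all genes (-6.94, adjusted p 0.0286, against 0.0846 to 1.00 in the others). The lists called by camera numbered 2 with the mean of at least 1000 reads, against 0 in the other settings, and both were lost within that set with an estimated correlation (adjusted p 0.775 for each) and fry (0.417 and 0.274). The legacy method does not enter camera, so its list results repeat the main ones. With 1 library left out, the glycolysis list passed only without normal replicate 2 (0.000709) and the matrix list only without normal replicate 1 (0.0163). The direction of several named genes rested on 1 library. Without each library in turn the log2 fold change ranged from -6.94 to 2.33 for Mettl3, -7.51 to 2.01 for Wtap and -0.36 to 0.75 for Alkbh5, negative without BPA replicate 1 alone. It ranged from -1.95 to 0.18 for Sqstm1, positive without BPA replicate 2, and from -2.31 to 0.46 for Becn1, positive without BPA replicate 2 (0.16) or normal replicate 1. Fto, reported at -0.01, ranged from -4.41 to 7.26 (normal replicate 1 left out; 0.91 without BPA replicate 2), and was 0.13 with DESeq2's size factors, 0.060 with no filter and 0.090 with DESeq2. The cause of the last 3 was not tested. The 12 genes higher in BPA named after the data were seen passed in DESeq2. This is no independent support, since they were chosen by smallest edgeR p from the same counts.

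Higher peaks outnumbered lower ones under the stricter adjusted p, the fold threshold, 1 peak per gene, removal of the constant and the exact test of reads, at 65.1% to 70.9%. These settings reuse the same pooled values and are no independent support. The stricter adjusted p kept 3299 of 3331 peaks, so it could hardly move the split. The exact test takes reads as independent and leaves out the spread between replicates. With more than 10 reads in all 4 columns 799 were higher and 563 lower (58.7% higher), because the minimum removes peaks with few BPA input reads, which most higher peaks have. With input reads scaled by the spread between replicates 26 were higher and 121 lower, which says nothing on direction: BPA input reads were divided by 624 and normal ones by 210, so higher peaks with few BPA input reads cannot pass by construction. The difference in RNA between genes with higher and lower peaks stayed negative, from -0.49 to -0.35 without each library, and was -0.029 with direction from the IP alone. The gene-level m6A test and its 4 alternatives were not run. Low counts limit the BPA input most, with 10 or fewer reads in 1658 of 3331 peaks.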

Other observations

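The tests of spread between replicates, of matched random lists and of carried-over reads were chosen only after the result was seen. The others were written before their deciding values were seen, though the reads of Map1lc3b and the share of peaks with few input reads were known.

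Replicate libraries of a group disagreed far beyond counting error. A difference in sequencing depth is argued against: 37.1% of genes with a mean of at least 100 reads in the BPA pair, after scaling to library size, had 10 or fewer reads in 1 library, and 9.75% in the normal pair. Few RNA molecules amplified many times may account for it, since the mean variance-to-mean ratio rose only 1.11-fold from 1000-3000 to 3000-10000 reads in the BPA pair (1.81-fold in the normal pair) while the mean rose 2.87-fold. At 1000-3000 reads that ratio was 2.97 times as high in the BPA pair as in the normal pair, but above 10000 reads it was lower (886 against 1458), and with 1 pair per condition a wider spread between BPA cultures cannot be told apart from a lower yield of those libraries.

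Peaks higher in BPA sat where the BPA input had few reads. The input changes of 2 peaks of the same gene had a Spearman correlation of 0.099995 over 1632 pairs in 679 genes. That value cannot decide on loss of the whole RNA. Sparse reads, with a median of 11 per peak in the BPA input, lower it either way, and the peaks were selected by IP over input. Of 1243 such peaks, 80.4% lay in genes whose BPA level was at least 0.5 times the normal level. For those genes this argues against loss of the whole RNA and leaves patchy input coverage within the transcript as a candidate explanation. Loss of the whole RNA stays open for genes such as Map1lc3b and Rb1cc1, with 2 and 2 and with 9 and 3 BPA reads. Other higher peaks had 85.3%, so the 80.4% does not set the peaks with few BPA input reads apart. More methylation of these RNAs stays open: 52.4% of 1016 peaks with at least 100 reads in all columns were higher (40.8% without the constant), but that minimum leaves none of the peaks in question.

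Map1lc3b and other autophagy genes had few reads in BPA. Map1lc3b was not alone in this: 17.1% (exact 95% interval 14.9% to 19.3%) of genes at a comparable normal level had 10 or fewer reads in both BPA libraries. Genes lowered by BPA would be counted in that share, so it cannot tell chance absence in sparse libraries from a fall. For the list, its median lay at the 5.49th percentile of 10000 random lists matched on normal level, above a limit of 5 that was set after the result was seen, with a median of -0.20 in those lists. A test of reads carried over between the BPA libraries, whose share changed 1.92-fold over levels, ran on genes abundant in the other BPA library and says nothing about Map1lc3b, which is low in both. At the peaks of Map1lc3b and Rb1cc1 the BPA IP held 784 and 652 reads, where the BPA input held 4 and 3. It held 1286 and 893 reads at the pair of Nbr1 peaks, where the BPA input held 11 and 34, but 0 at the Uvrag peak. The low BPA counts of Map1lc3b and Rb1cc1 were thus not matched in the IP, though these peaks were selected by IP over input. A fall of autophagy RNA caused by BPA stays open.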
